A study of Homo sapiens with 32 samples.

How the data were processed

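The series holds 32 libraries of chromatin-associated RNA, 16 of MeRIP and 16 of input, from 4 cell lines, with 2 MeRIP libraries per group. The 12 peak lists were analysed. Per the labels' protocols, RNA was enriched with an m6A antibody kit after adding spike-in RNA, and stranded libraries were sequenced as paired reads. Spike-in values were not used here. Per the submitters' processing notes, Trim Galore 0.6.6, Bowtie2 2.4.2, HISAT2 2.1.0 and MACS2 2.2.7.1 were used, with no role or order given, and the build is hg38.

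For OVCAR8 and SKOV3 the authors deposited 1 peak list per MeRIP library, with peaks called separately on each strand according to the peak names. Each peak has a fold enrichment (a linear ratio) as deposited by the authors, and the deposited p and q values are on a −log10 scale. The lowest −log10 q in these lists was 2.00. For LOVO and RKO the authors deposited 1 list per group with a score per peak, which no header explains. In these lists no score was below 3, the peak names cite replicate 1, and between 339 and 1104 peaks of a list repeat the name of another. The highest numbers in the names exceeded the number of peaks, so some called peaks are not listed. How replicate 2 entered these lists is not given in the sources used here, and they were taken as values of a group with no SD. Folds, scores and p values are the authors' own and served to describe, rank or filter peaks within a list and to read depth. Ranks, and the peak strength drawn from them, used −log10 p in OVCAR8 and SKOV3 and the score in LOVO and RKO. Strength is therefore not the same measure in all lines. Terciles for the odds ratios between pairs of lines used fold or score.

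The file record, library title, cell-line field and peak names gave the same line and condition for each list, so the mismatch between labels and peaks described in the results does not come from how lists were assigned to groups here. Groups were kept as labelled, and no list was moved to another group.

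Depth was read from the values. Fold and p give the reads at a summit and the background if the caller used a Poisson tail and added 1 to both. In all 8 lists with p values, 100% of summits then came out as whole reads, within a tolerance of 10% of the step of 1 read. The background from the fold values alone, taken as the smallest that puts the 40 most frequent values on whole reads, was used for LOVO and RKO and assumes that the score is such a fold. Read totals are not given in the sources used here.

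Peaks on chromosomes 1 to 22 and X were used. Regions are merged same-strand peaks present in every list of a group. A control region is lost if no knockdown peak overlaps it by 1 bp, and a knockdown region is gained if no control peak does. Intervals are 95% intervals from 2000 resamplings of the 23 chromosomes and cover the spread between chromosomes only. A peak or region was assigned to a gene of the RefSeq table of GRCh38.p14 if it overlapped only that gene's body. Peaks in several genes, 11.4% to 13.1% of a list, were left out. The table gives no exons, strands or repeats and no genome sequence was used, so gene features were reduced to 4 classes by gene body. Shares of peaks by class used the peak midpoint, and loss by class used any overlap of a region by 1 bp. Where genes overlapped, protein-coding genes came first and long non-coding RNA genes next. The planned shares of peaks over LINE-1, at untranslated regions or stop codons and with the DRACH motif were not analysed here.

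Peak numbers, class shares and gene lists were tested with a two-sided exact permutation test in which labels were permuted within each line and the statistic was the mean over lines of the knockdown minus control difference, 144 arrangements in all. Peak numbers were taken as log2. A list's value was log2 of its peaks plus 1 over all gene-assigned peaks. Benjamini-Hochberg adjustment was over the 4 classes or the 19 lists. For each list and line, the percent of control regions lost was also placed among 10000 random lists of genes matched on the number of control regions. In an alternative added after seeing the data, the loss expected of each control region was that of all regions in the same 10% of peak strength, the mean rank of its strongest peak within each control list, and random lists were drawn on observed minus expected loss. On simulated data in which loss depended on strength alone, the observed minus expected loss of 2000 strong LOVO regions was -0.358 percentage points, where 0 was simulated. Loss there was drawn from the very value used as strength. The simulation thus checks the code and not whether strength is fully held alike in the real lists.

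The gene lists and the rule for the genes named were fixed before the data were examined. The rule took per line the 6 genes with most lost and the 4 with most gained regions among genes whose peak number differed that way between every knockdown and every control list, the 8 genes lost in all 4 lines with the highest smallest number, METTL3, and from each list up to 4 members with most control regions. Of the last, only examples are printed, and 1 gene that the rule names is not reported here.

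The alternatives tried were a −log10 q of at least 5, all sequences, merged peaks, bases covered, equal numbers of peaks per list, other overlap and merging rules, OVCAR8 and SKOV3 only, a one-sided test, each replicate left out and a replicate block. Chosen after seeing the data were 1 stratum for both ovarian lines, lists without RKO or without the ovarian lines, a fold or score of at least 3, numbers in peak names, ignoring strand and giving overlapping genes' peaks to the protein-coding gene. The code was tested on simulated peak lists of 20000 regions. It returned 49.8%, 20.6%, 34.995% and 60.1% lost where 50%, 20%, 35% and 60% had been removed from lists laid out as OVCAR8, SKOV3, LOVO and RKO. Of 500 tests on random values for the 12 lists, 3.6% passed 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.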

Results

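N6-methyladenosine (m6A) was mapped by MeRIP-seq, in which RNA fragments are pulled down with an m6A antibody, on chromatin-associated RNA of 4 human cancer cell lines. OVCAR8 and SKOV3 are ovarian cancer lines, and LOVO and RKO are colorectal cancer lines. Lists of each line were labelled as control or as knockdown of METTL3, the catalytic subunit of the m6A methyltransferase. For OVCAR8 and SKOV3, 2 peak lists per group were analysed, and for LOVO and RKO 1 list per group, with no replicates. On chromosomes 1 to 22 and X the control lists held 28237 and 28774 peaks in OVCAR8, 28918 and 29102 in SKOV3, 36242 in LOVO and 37398 in RKO. The knockdown lists held 15484 and 15744 peaks in OVCAR8, 26178 and 26865 in SKOV3, 31060 in LOVO and 34015 in RKO. The caller's genome-wide background, which scales with the MeRIP reads of a library, was 0.982 times the control value in OVCAR8 knockdown, 0.955 times in SKOV3, 1.15 times in LOVO and 0.483 times in RKO. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these lists, which may be technical.

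The targeted gene and the sharing of peaks between lists were examined first, as a check of the labels. METTL3 (chromosome 14, 21498138 to 21511340, GRCh38) carried 0 and 1 peaks in OVCAR8 control, 1 and 1 in OVCAR8 knockdown, 1 and 3 in SKOV3 control, and 0 and 0 in SKOV3 knockdown. It had 2 peaks in LOVO control and 2 after knockdown, and 2 and 3 in RKO. A peak marks methylation on a transcript that is present and does not measure its level, so these values do not check the knockdown. RNA levels in the input libraries were not analysed here. Lost and gained regions below therefore cannot be told apart from differences in RNA level. The cell-line labels of the ovarian lists were at odds with the peaks. The libraries labelled OVCAR8 knockdown shared 95.9% of their peaks with SKOV3 control lists and 69.3% with OVCAR8 control lists (means of 4 pairs of lists each). The libraries labelled SKOV3 knockdown shared 81.9% of their peaks with OVCAR8 control lists and 56.5% with SKOV3 control lists. Replicates of one group shared 85.05% to 91.3%. Across 13978 genes, which are not independent replicates, peaks per gene correlated at a mean Spearman rho of 0.90 between OVCAR8 control and the libraries labelled SKOV3 knockdown, and of 0.56 between OVCAR8 control and the libraries labelled OVCAR8 knockdown. Between SKOV3 control and the libraries labelled OVCAR8 knockdown the mean rho was 0.79, and with those labelled SKOV3 knockdown 0.57. The list labelled RKO knockdown stood apart from all the others. It shared 45.1% of its peaks with RKO control and 43.02% with LOVO control, and its rho was 0.39 with RKO control and 0.41 with SKOV3 control. LOVO was the only line whose knockdown list was closest to its own control by both measures, with 73.1% of peaks shared and a rho of 0.82. The groups are those of the labels throughout, so each direction within OVCAR8, SKOV3 or RKO is drawn from lists that these values call into question.

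**Figure D1:**
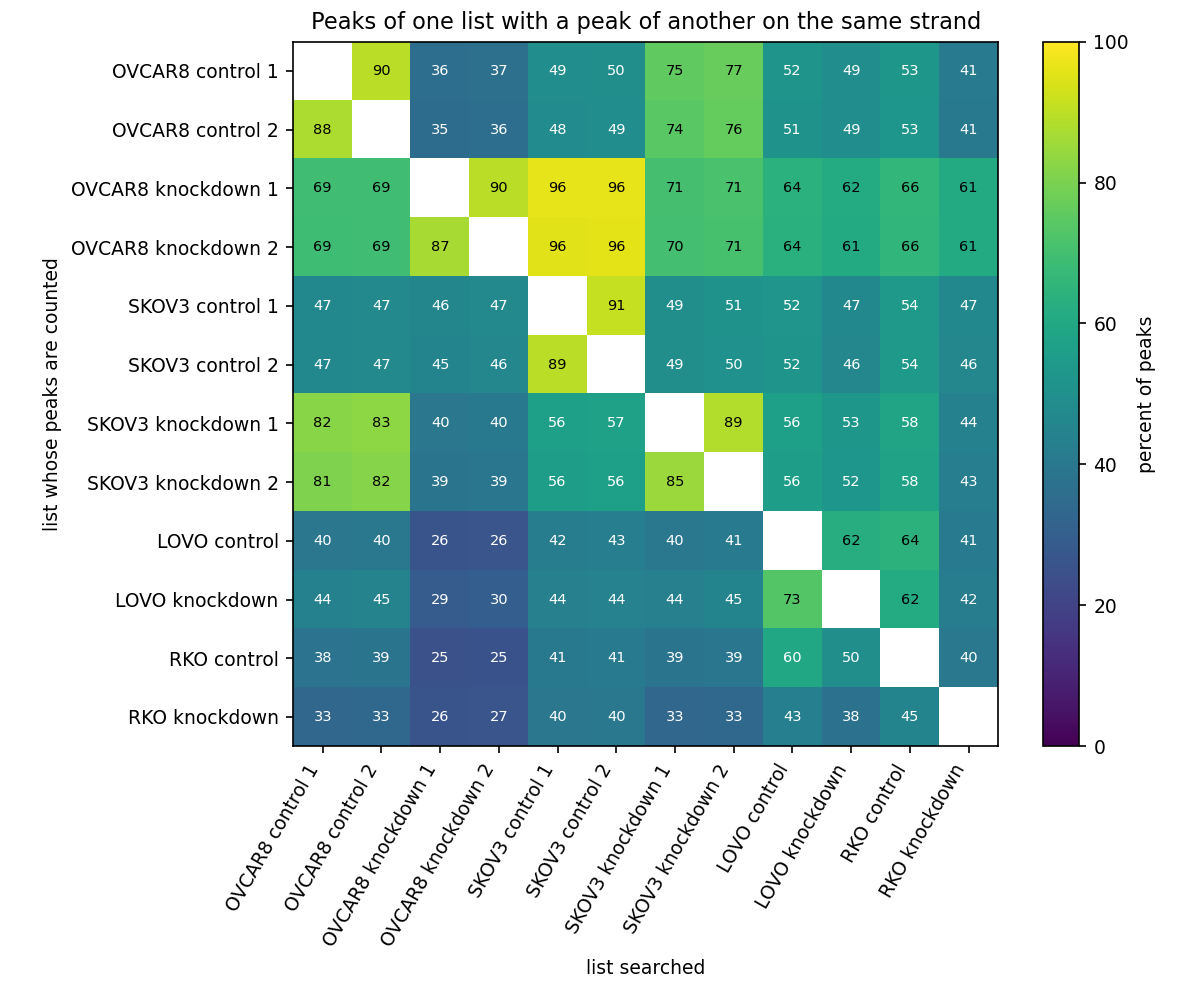
Percent of the peaks of one list (rows) that overlap a peak of another list (columns) on the same strand by at least 1 bp, for all 12 lists named as labelled. The libraries labelled OVCAR8 knockdown share a mean of 95.9% with SKOV3 control, those labelled SKOV3 knockdown share 81.9% with OVCAR8 control, and the list labelled RKO knockdown shares 45.1% with RKO control.

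The first comparison asked whether knockdown of the methyltransferase lowered the number of m6A peaks. Peak number fell in the knockdown lists, with fewer peaks in all 4 lines as labelled and a mean log2 difference over lines of -0.34, a ratio of 0.790. This passed the exact stratified permutation test (two-sided, p = 0.0139, the smallest that its 144 arrangements can give). The mean is the same whichever ovarian line a knockdown group came from, since both lines weigh the same. With the 8 ovarian lists permuted as 1 stratum, so that their line labels were not used, the two-sided exact permutation p was 0.00714, the smallest possible. With OVCAR8 and SKOV3 only, the difference was -0.50 and the two-sided exact permutation p was 0.0556, the smallest possible. With LOVO and RKO only it was -0.18, and the two-sided exact permutation p was 0.5, again the smallest possible.

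The size of the difference varied from line to line. Peak number was 45.2% lower in the libraries labelled OVCAR8 knockdown, with 28506 ± 380 peaks in control and 15614 ± 184 in knockdown (SD, n = 2 each). In SKOV3 it was 8.59% lower, with 29010 ± 130 peaks in control and 26522 ± 486 in the libraries labelled knockdown (SD, n = 2 each). In both lines each knockdown list lay below each control list, and the two-sided exact permutation p was 0.333, the smallest that 2 lists against 2 allow. In LOVO the number was 14.3% lower and in RKO 9.05% lower. In bases covered, the log2 difference was -0.25 in SKOV3, where peak number gave -0.13, and -0.23 in RKO, where it gave -0.14. The highest peak numbers in the peak names, which exceed the peaks listed, gave -0.028 in LOVO in place of -0.22, and -0.34 in RKO. The log2 difference in OVCAR8 minus that in SKOV3 was -0.74, and permuting line labels within each condition gave a two-sided exact permutation p of 0.333, where 0.0556 was the smallest possible. The control lists of both lines held nearly as many peaks, so exchanging control labels hardly moved the statistic. This p does not show that the lines did not differ, and the test rests on the line labels questioned above.

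**Figure D2:**
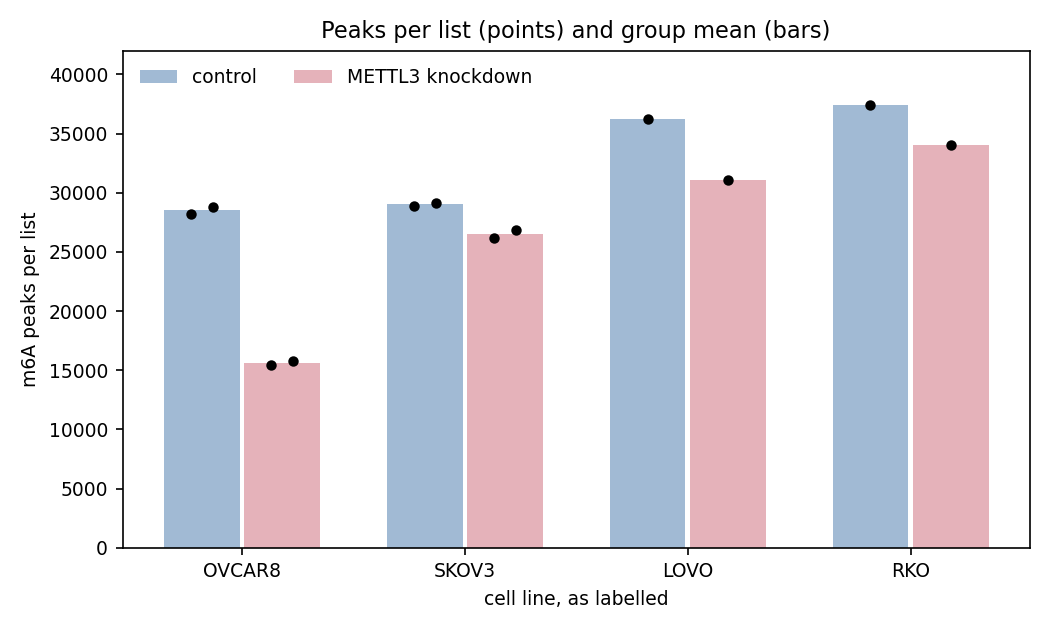
Number of m6A peaks per list on chromosomes 1 to 22 and X (points) and the group mean (bars), by cell line and condition as labelled. Knockdown lists lie below control lists in each line, by 45.2% in OVCAR8, 8.59% in SKOV3, 14.3% in LOVO and 9.05% in RKO.

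In LOVO, the genes with most lost regions included protein-coding genes, long non-coding RNA genes and a pseudogene, each with a small part of the 13696 regions lost. PRELID2 (chromosome 5, 145228985 to 145835342) had 31 peaks in control and 12 after knockdown, and the long non-coding RNA gene LOC107985962 (chromosome 2, 175595435 to 175839038) had 30 and 9. SLC38A4-AS1, an antisense transcript gene, had 28 and 9 peaks, XKR9 37 and 24, the pseudogene DPY19L2P2 28 and 12, and CCSER1 35 and 25. In the other direction, MAD1L1, a spindle checkpoint gene, had 21 peaks in control and 37 after knockdown, ABR 13 and 27, and FAM20C, a secretory kinase gene, 13 and 27. Of 36242 control regions, 37.8% had no knockdown peak (95% interval from resampled chromosomes 35.7 to 39.7), and 26.9% of 31060 knockdown regions had no control peak. The loss was 36.3% of regions in protein-coding genes, 46.9% in long non-coding RNA genes (interval 42.5 to 51.4) and 50.4% between genes. Weak peaks were lost most often: 63.7% of the lowest-scoring 10% of control peaks and 3.61% of the highest-scoring 10% had no knockdown peak. With 1 list per group there is no replicate to set these values against.

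In the comparison labelled OVCAR8, the genes with most lost regions went from many peaks to none or nearly none. MIR3667HG, a long non-coding RNA gene (chromosome 22, 49414524 to 49657519), had 118 and 120 peaks in the control lists and 0 and 0 in the libraries labelled knockdown. The phosphodiesterase gene PDE10A had 76 and 75 against 0 and 0, the olfactory receptor gene OR51B5 62 and 65 against 0 and 0, the transcription factor gene GLIS3 54 and 55 against 0 and 0, PDE4D 56 and 54 against 1 and 1, and SLCO3A1 51 and 49 against 0 and 0. Among gained genes PTPRN2, of the receptor phosphatase family (chromosome 7, 157539056 to 158587823), had 0 and 0 peaks in control and 59 and 58 in the libraries labelled knockdown. WDPCP had 2 and 2 against 39 and 38, RGS12 0 and 0 against 21 and 19, and DIP2C 0 and 0 against 18 and 18. Of 24666 control regions 57.8% were lost (interval 54.3 to 61.5), and 25.9% of 13463 knockdown regions were gained, where 10.4% to 13.02% of one replicate's peaks were missing from the other. With equal numbers of peaks per list, lost regions were 71 against 108 in MIR3667HG, 45 against 68 in PDE10A and 23 against 49 in PDE4D. They were 38 against 57 in OR51B5, 38 against 49 in GLIS3 and 31 against 46 in SLCO3A1. In SKOV3 control MIR3667HG had 0 and 0 peaks and PTPRN2 88 and 87. Set against the knockdown lists of each line in turn, OVCAR8 control regions had no peak for 57.8% in OVCAR8, 14.6% in SKOV3, 48.1% in LOVO and 56.7% in RKO.

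In the comparison labelled SKOV3, several of the same loci went the other way. PTPRN2 had 88 and 87 peaks in control and 0 and 0 in the libraries labelled knockdown, and the potassium channel gene KCNQ5 (chromosome 6, 72622064 to 73198853) 62 and 62 against 0 and 0. The phospholipase gene PLCB4 had 47 and 47 against 0 and 0, WDPCP 48 and 48 against 2 and 2, the cadherin gene CDH4 45 and 49 against 1 and 3, and LOC124900404 36 and 37 against 0 and 0. MIR3667HG had 0 and 0 in control and 77 and 81 in the libraries labelled knockdown, PDE10A 0 and 0 against 55 and 52, the collagen gene COL5A1 0 and 0 against 29 and 34, and CTIF 1 and 1 against 32 and 34. Of 25545 control regions 44.4% were lost (interval 40.5 to 48.1), and 36.5% of 22438 knockdown regions were gained, where 8.73% to 14.95% of one replicate's peaks were missing from the other. Set against the knockdown lists of each line in turn, SKOV3 control regions had no peak for 44.3% in OVCAR8, 44.4% in SKOV3, 51.3% in LOVO and 50.9% in RKO. Of the regions of the libraries labelled OVCAR8 knockdown, 1.94% had no SKOV3 control peak (interval 1.45 to 2.48).

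In RKO, whole genes differed between the 2 lists. ZC3H12B (chromosome X, 65034826 to 65507887) had 70 peaks in control and 0 in the list labelled knockdown, CFAP299 45 and 0, ARHGAP22 31 and 0, SCAPER 37 and 6, FHIT 38 and 9, and TRAPPC9 38 and 7. ADARB2, of the RNA-editing enzyme family (chromosome 10, 1177313 to 1737525), had 0 in control and 87 in the list labelled knockdown, HIVEP3 3 and 68, SNTG1 0 and 58, and the cadherin-related gene FAT3 0 and 49. ADARB2, SNTG1 and FAT3 had 0 peaks in every other list of the 12. Of 37398 control regions 60.1% were lost (interval 57.2 to 62.1), and 54.9% of 34015 knockdown regions were gained, where the background of the knockdown list was 0.483 times that of control. Among the highest-scoring 10% of control peaks, 25% were lost, against 3.61% in LOVO.

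**Figure D3:**
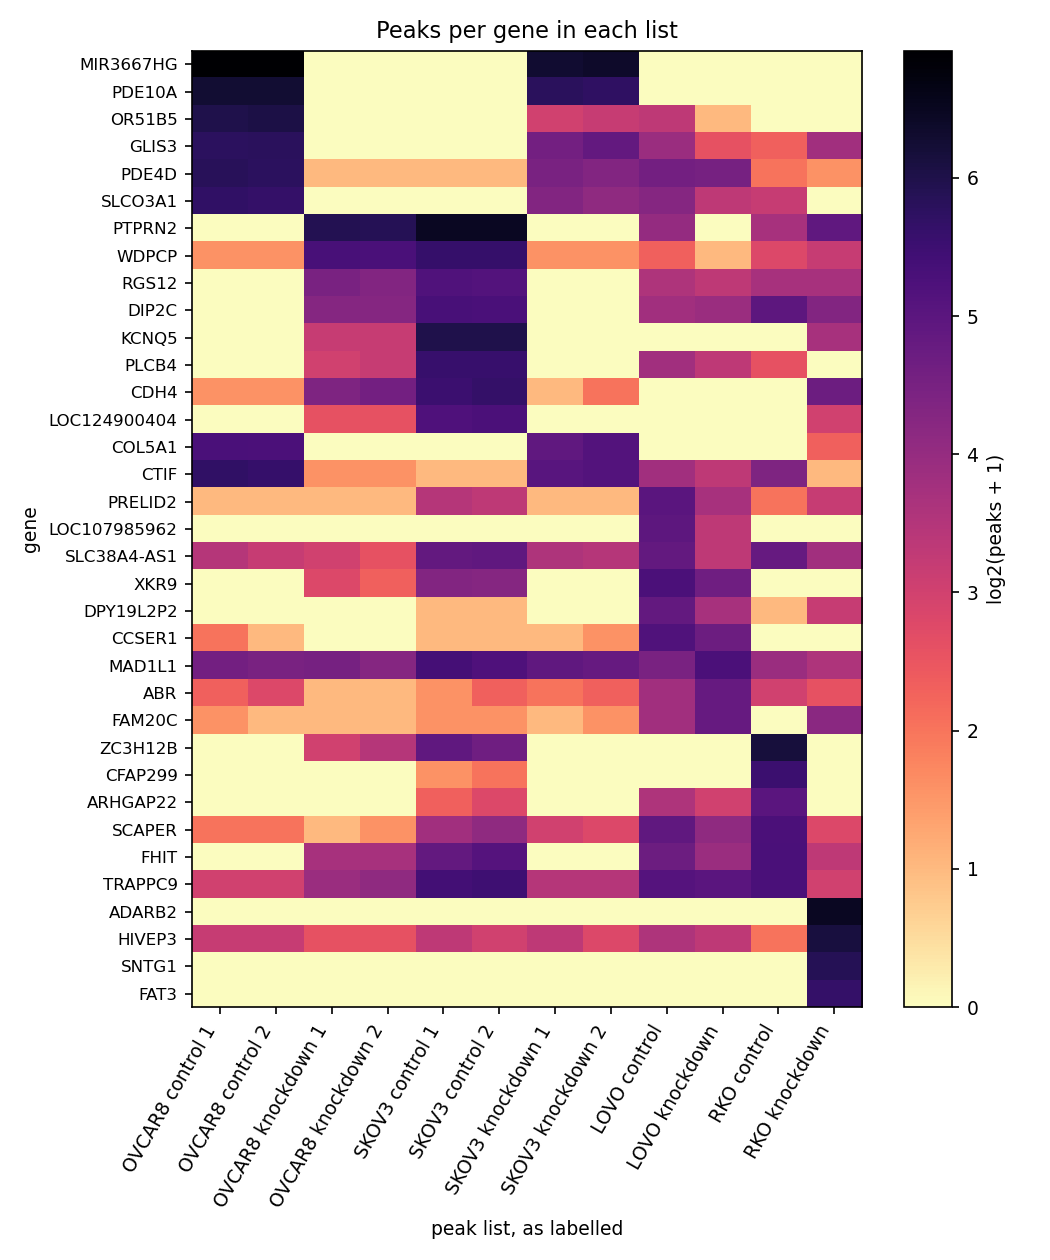
Peaks per gene, as log2(peaks + 1), in each of the 12 lists as labelled, for the genes with most lost or gained regions in a line. MIR3667HG has 118 and 120 peaks in OVCAR8 control and 77 and 81 in the libraries labelled SKOV3 knockdown, PTPRN2 has 88 and 87 in SKOV3 control and 59 and 58 in the libraries labelled OVCAR8 knockdown, and ADARB2 has 87 in the list labelled RKO knockdown.

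Genes with a lost region in all 4 lines as labelled numbered 373, or 135 with equal numbers of peaks per list and 674 with regions of any control list. The 8 with the highest smallest number over the lines were TENM3, GSE1, EHBP1, EXOC6B, SBF2, SIPA1L3, GPHN and the long non-coding RNA gene LINC-PINT. This ranking counts lost regions, so it favours genes with many regions. How many of the 373 would arise by chance was not computed. TENM3, a teneurin adhesion gene (chromosome 4, 181447613 to 182803024), lost 8 of 10 control regions in OVCAR8, 8 of 11 in SKOV3, 7 of 10 in LOVO and 8 of 11 in RKO. LINC-PINT lost 13 of 15, 23 of 31, 4 of 8 and 10 of 12. SIPA1L3 lost 5 of 18, 10 of 31, 6 of 17 and 10 of 17. In each line this was a smaller part than of all control regions, where TENM3 and LINC-PINT lost a larger one. GPHN, a synaptic scaffold gene, had 23 peaks in LOVO control and 11 after knockdown, and EXOC6B 23 and 9. GSE1 had 23 and 26 in LOVO, and 13 and 14 in OVCAR8 control against 14 and 15 in the libraries labelled knockdown. In SKOV3 and RKO as labelled, GSE1 had fewer peaks in knockdown. With equal numbers of peaks per list, EHBP1 and EXOC6B lost 0 regions in OVCAR8, against 6 and 11 with all peaks, and so were not lost in all 4 lines. In OVCAR8 the others then lost fewer too: GPHN 2 against 16, SBF2 2 against 11, GSE1 4 against 9, TENM3 5 against 8, SIPA1L3 3 against 5 and LINC-PINT 7 against 13. In LOVO, LINC-PINT lost 1 against 4 and GSE1 3 against 6. Other settings gave more lost regions. With regions of any control list, EHBP1 lost 14, EXOC6B 18 and SBF2 19 in OVCAR8, and in SKOV3 GSE1 lost 40 against 26 and GPHN 9 against 4. Where absence from 1 knockdown list sufficed, EXOC6B lost 9 against 5 in SKOV3, SBF2 10 against 5 and GPHN 7 against 4, and where 50% of a region had to overlap, EXOC6B lost 8. Among regions that both lines of a pair held in control, those lost in one line as labelled were lost more often in the other. The odds ratio was 3.51 between OVCAR8 and LOVO (95% interval 3.16 to 3.88) and 3.34 between SKOV3 and LOVO (3.03 to 3.65). It was 5.18 between OVCAR8 and RKO (4.69 to 5.68), 2.90 between SKOV3 and RKO (2.501 to 3.32), 2.63 between LOVO and RKO (2.42 to 2.85) and 2.76 between OVCAR8 and SKOV3 (2.05 to 3.72). Between OVCAR8 and SKOV3, 116 of 12191 shared regions were lost in both lines, 2262 in OVCAR8 only and 179 in SKOV3 only, and 9634 were kept in both. Most shared regions lost in OVCAR8 were thus kept in SKOV3 as labelled. Weak peaks were lost more often in each line. Combining terciles of fold enrichment in the first OVCAR8 control list gave 1.67 for OVCAR8 and SKOV3. Strength in SKOV3 was not held alike, so this does not show shared loss beyond peak strength.

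By gene class, no share of peaks passed the test. The knockdown minus control difference, as the mean over lines, was -0.64 percentage points for protein-coding genes, 0.12 for long non-coding RNA genes, 0.099 for other genes and 0.42 between genes (two-sided exact stratified permutation tests, adjusted p = 1 for each of the 4 classes, smallest unadjusted p possible 0.0139). The lines differed in sign. In LOVO the protein-coding share was 86.2% in control and 88.7% after knockdown, and in SKOV3 83.3% ± 0.024 and 86.8% ± 0.10 in the libraries labelled knockdown (SD, n = 2 each), while in RKO it was 88.4% and 80.2%. Without the RKO lists, an alternative added after seeing the data, the differences were 1.87 points for protein-coding genes, -0.76 for long non-coding RNA genes and -1.17 between genes. Two-sided exact permutation tests then gave adjusted p = 0.222, 0.0556 and 0.0556, the lowest of the ranges over all alternatives, which reached 1 for each. With the RKO lists left out, the smallest unadjusted exact permutation p possible was 0.0278. An adjusted 0.0556 is what 2 of the 4 classes at that limit give.

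Of the 19 gene lists, 0 passed the adjusted threshold of 0.05 in the two-sided exact permutation test, whose smallest p is 0.0139, and 2 had an unadjusted p under 0.05. The share of gene-assigned peaks in immediate-early and MYC family genes was 0.22 higher on the log2 scale, higher in 4 of 4 lines, with an exact permutation p of 0.0139 and an adjusted p of 0.264, so a single list at the smallest p could not pass. The number of peaks in these genes was lower in 3 of 4 lines, at a mean of 51.5 in control and 38.5 in knockdown lists in OVCAR8, 66 and 64 in LOVO and 68 and 60 in RKO, and 56 and 58.5 in SKOV3. MYC had 4 and 5 peaks in OVCAR8 control, 5 and 4 in the libraries labelled OVCAR8 knockdown, and 4 in LOVO control and 5 after knockdown, while FOSL1 had 3 and 4 in LOVO and 5 and 0 in RKO, and ATF3 5 and 3 in LOVO. The share in replication-dependent histone genes was 0.31 higher, also in 4 of 4 lines (exact permutation p = 0.0278, adjusted p = 0.264), on few peaks, with 2 in LOVO control and 2 after knockdown. With the 8 ovarian lists as 1 stratum, which does not use their line labels, only the immediate-early and MYC list had an unadjusted p under 0.05. Its two-sided exact permutation p was then 0.00714, the smallest possible (adjusted p = 0.136, from 0.088 to 1 over all alternatives), and that of the histone genes was 0.143 (adjusted p = 0.905, from 0.132 to 1). The differences for m6A writers (0.098, exact permutation p = 0.514) and for m6A readers and erasers (0.067, exact permutation p = 0.542) went both ways between lines. ZC3H13, a subunit of the writer complex, had 13 peaks in LOVO control and 11 after knockdown, VIRMA 4 and 5, YTHDC1, the nuclear m6A reader, 8 and 6, and the demethylase gene FTO 8 and 5. Ribosomal protein genes had a difference of 0.70 (exact permutation p = 0.0972) and nuclear long non-coding RNA genes of 0.058 (exact permutation p = 0.931), with PVT1 at 9 and 7 peaks in LOVO and LINC-PINT at 8 and 6.

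In LOVO, genes of histone methylation enzymes lost 21.2% of 208 control regions, where random lists with as many regions per gene lost a median of 38.8%, and none of 10000 random lists lost as few. Random lists were not matched on peak strength, and a low loss was not particular to this group, since 13 of 17 lists lay below the random median in LOVO. From the strength of each region, a comparison added after seeing the data, the loss expected of these genes in LOVO was 32.6%. By this measure too, 13 of 17 lists in LOVO lost less than expected. The observed minus expected loss of histone methylation enzymes stood at percentile 0.14 of random lists. The same list lost 39.9% in OVCAR8, 14.6% in SKOV3 and 53.5% in RKO as labelled, at percentiles 0.08, 0.01 and 0.535 of random lists, or 0.63, 0.04 and 1.14 given peak strength. KMT2D, a histone H3 methyltransferase gene, lost 1 of 16 regions in LOVO, SETD1B 0 of 13, NSD2 3 of 17 and ASH1L 5 of 13. Genes of histone acetyltransferases and BET proteins stood at percentiles 1.94, 0.75, 4.495 and 10.995 in OVCAR8, SKOV3, LOVO and RKO, and chromatin remodellers at 0.485, 0.01, 6.82 and 5.25. Given peak strength the acetyltransferases stood at 3.25, 2.01, 7.39 and 12.6, and the remodellers at 3.01, 0.06, 12.4 and 7.80. The remodellers lost 60.9% in RKO, above the 59.5% expected. Lists of other genes stood low in single lines too. In LOVO, heterochromatin and LINE-1 silencing genes stood at percentile 1.51, or 0.42 given peak strength. Immediate-early and MYC family genes in RKO stood at 0.015, or 0.07. Neither of these lists stood as low in every line. ZNF zinc-finger genes lost 27.8% in OVCAR8, 40.8% in SKOV3, 31.8% in LOVO and 35.1% in RKO, where random lists lost medians of 50.1%, 37.2%, 35.995% and 57.9%. They stood at percentiles 0, 92.2, 1.46 and 0 of random lists, or 0, 99.7, 35.8 and 0 given peak strength. The loss of ZNF genes expected from peak strength in SKOV3 was 41.3%, so the high percentile there came with a loss near that expected. These percentiles describe the lists at hand and are no test across replicates, and those of OVCAR8, SKOV3 and RKO rest on the labels questioned above.

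Some marker genes went with the sharing of peaks between lists. The log2 difference of the ovarian and Muellerian epithelial markers was -0.92 in OVCAR8 and 1.24 in SKOV3 as labelled. PAX8, a lineage transcription factor gene, had 6 and 6 peaks in OVCAR8 control, 0 and 0 in the libraries labelled OVCAR8 knockdown, 2 and 2 in SKOV3 control and 5 and 4 in the libraries labelled SKOV3 knockdown. The intestinal transcription factor gene CDX2 had 4 peaks in LOVO control and 3 after knockdown, 3 and 0 in RKO, and 0 in the 8 ovarian lists. Fibroblast and immune marker genes held few peaks, with COL1A1 at 4 and 3 in SKOV3 control and 3 and 2 in the libraries labelled OVCAR8 knockdown. The mean log2 differences of the remaining lists were 0.13 for the nuclear exosome, -0.061 for homologous recombination, -0.097 for end joining and 0.033 for excision and mismatch repair. They were 0.018 for histone acetyltransferases, 0.092 for histone methylation enzymes, -0.083 for chromatin remodellers, -0.064 for heterochromatin and LINE-1 silencing and 0.26 for ZNF genes. They were 0.18 for intestinal markers, 0.38 for fibroblast and immune markers, 0.047 for ovarian markers and 0.064 for the cell cycle, and each of these 13 lists had a two-sided exact permutation p between 0.167 and 1.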

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

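The tests in this part were chosen after the result was seen, except those on the highest-scoring 10% of peaks in RKO and on other splits of the 8 ovarian lists. For the genes, lists and classes that follow, OVCAR8 and SKOV3 went opposite ways as labelled, with each knockdown list on one side of each control list. That difference was not tested. The value given is the OVCAR8 difference (knockdown minus control) minus the SKOV3 difference. In mean peaks per gene it was -198 for MIR3667HG, -129 for PDE10A, -71 for OR51B5, -80 for GLIS3, -73 for PDE4D, -67.5 for SLCO3A1, -69 for COL5A1 and -79.5 for CTIF. It was 146 for PTPRN2, 82.5 for WDPCP, 54.5 for RGS12, 56.5 for DIP2C, 70 for KCNQ5, 54.5 for PLCB4, 64.5 for CDH4 and 41.5 for LOC124900404. It was 23.5 for XKR9, 35 for ZC3H12B, 42.5 for FHIT and 40 for TRAPPC9. For log2 shares of lists it was 0.97 for m6A writers, 0.92 for m6A readers and erasers, 0.68 for homologous recombination, -0.51 for heterochromatin and LINE-1 silencing and -0.42 for nuclear long non-coding RNAs. It was -2.16 for ovarian markers, 3.45 for fibroblast and immune markers, -0.98 for the cell cycle and 1.31 for ZNF genes. In percentage points of peaks it was -3.79 for protein-coding genes and 1.76 for other genes. Peaks outside chromosomes 1 to 22 and X, which no comparison used, were more numerous in knockdown than in control in SKOV3 and RKO as labelled. They numbered a mean of 16.5 per knockdown list in SKOV3 and 13 in RKO, against 9 and 7 in SKOV3 control and 3 in RKO control. In OVCAR8 they were fewer, at 30 and 28 in control and 21 and 22 in knockdown, and in LOVO too, at 46 and 34. Across the 8 ovarian lists, 117 regions were in all lists of one condition and in none of the other. Of the 35 splits into 4 and 4 lists, 3 gave as many, the split by condition included. The split by line labels gave 572 and that of OVCAR8 control with the libraries labelled SKOV3 knockdown 8458, the highest, which point to a structure of the samples other than condition. The remaining 32 splits gave at most 50. The count of 3 was set by that structure, so it neither excludes chance nor speaks for it.

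The ovarian knockdown lists resembled the control of the other line. A response shared by both lines would not by itself give opposite differences, and the difference in peaks per gene correlated at -0.66 between the lines as labelled, across 13978 genes, but this restates the resemblance, and a shared response beneath another cause stays open. An exchange of line labels, of the knockdown or of the control lists, is a candidate explanation that cannot be told apart from mixed cultures. Each of the 4 knockdown lists shared more peaks with the other line's control, by at least 25.1 percentage points. This is the resemblance itself and no separate test. Cells of the other line mixed into the cultures stay open too: of genes with 5 or more peaks in both control lists of one line and none in the other line, 23.05% for SKOV3 and 13.5% for OVCAR8 had a peak in the libraries labelled as that line, against 91.4% and 99.5% in those labelled as the other. A response to knockdown that differs between the lines was not tested. By itself it would have to replace each line's peaks with those of the other line's control. The percents just given, over both sets of genes, argue against it as the whole source of the resemblance. Such a response beneath another cause stays open.

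The list labelled RKO knockdown stood apart from all the others. The tables argue against lower depth for the gained peaks, since the highest-scoring 10% of knockdown peaks were found in the deeper control list 64.6% of the time, against 95.6% in LOVO, a difference of -31.0 points (interval -35.6 to -26.4). For the lost peaks lower depth cannot be told apart: the highest-scoring 10% of control peaks were found less often than in LOVO, a difference of -21.4 points, but its interval of -23.5 to -19.4 includes the bound of -20 that would argue against it. Cells of another origin or a strongly diverged clone are a candidate explanation, with 92 genes of 10 or more peaks in that list and none in RKO control, against 0 in LOVO. A response of RKO to knockdown cannot be told apart from this with 1 list per group, although 2.17% of those genes had more peaks in LOVO knockdown than in LOVO control.

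The libraries labelled OVCAR8 knockdown had the fewest peaks. The tables argue against lower MeRIP depth, since their background was 0.863 times that of SKOV3 control and 0.982 times that of OVCAR8 control. A higher input background cannot be told apart: a first comparison, in which peaks above the background floor were lost less often than peaks at it (42.2% against 52.1% of SKOV3 control peaks, 43.99% against 68.1% of OVCAR8 control peaks), argued against it but set peaks of unlike strength side by side. It was replaced by one within 10 bins of −log10 p, which gave -3.70 points for SKOV3 control and -19.6 for OVCAR8 control, where under -5 for both would argue against it. Loss of methylation after knockdown may account for the low number and stays open, as does a difference between the lines.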

How the results depend on the processing

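Alternatives without the RKO lists, without the OVCAR8 and SKOV3 lists, by peak names and with the protein-coding gene first were chosen after the data were seen. The lower peak number over the 4 lines kept its direction under all alternatives run, and its side of the threshold except with OVCAR8 and SKOV3 only (-0.50) and without the OVCAR8 and SKOV3 lists (-0.18), where fewer arrangements allow no p under 0.05. With the replicate block it was -0.34 (two-sided exact permutation p = 0.0313, the smallest possible). Across regions, same-numbered libraries did not deviate together (correlations 0.0020 in OVCAR8 and -0.0056 in SKOV3, 2 pairs each). In each ovarian group, however, replicate 2 had more peaks and a higher background than replicate 1. These correlations therefore do not show that same-numbered libraries share only a number. The LINE-1, DRACH, exon and summit alternatives were not run. In bases covered, LOVO gave -0.25 and RKO -0.23, and by peak names -0.028 and -0.34. The lack of replicates limits each LOVO and RKO value.

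The percent of control regions lost in OVCAR8, SKOV3, LOVO and RKO was 64.9, 50.7, 44.2 and 66.7 when 50% of a region had to overlap. With equal numbers of peaks per list it was 44.5 in OVCAR8 and 33.8 in LOVO, and the genes with a lost region in all 4 lines numbered 135 in place of 373, or 674 with regions of any control list. In OVCAR8 and SKOV3 it was 63.7 and 48.6 with regions of any control list, 63.5 and 50.4 when absence from 1 knockdown list sufficed, and 60.3 to 61.4 and 46.7 to 47.99 with a replicate left out. The odds ratio of shared loss with terciles combined was 1.67 for OVCAR8 and SKOV3, 2.89 for OVCAR8 and LOVO, 4.48 for OVCAR8 and RKO, 2.82 for SKOV3 and LOVO, 2.29 for SKOV3 and RKO and 1.92 for LOVO and RKO. The terciles were of fold or score in the first control list of the line named first in each pair. Strength in the other line was not held alike, so these ratios do not show shared loss beyond peak strength. With reciprocal overlap the odds ratio was 4.10 for OVCAR8 and LOVO, 5.82 for OVCAR8 and RKO and 3.46 for LOVO and RKO. The cause was not tested for any of these.

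Shares by gene class, none past the threshold, had the other sign with OVCAR8 and SKOV3 only, at 1.60 points for protein-coding genes, -0.62 for long non-coding RNA genes and -1.13 between genes, and without the RKO lists, at 1.87, -0.76 and -1.17. Gene lists had the other sign as follows. Counting genes with at least 1 peak: exosome -0.013, homologous recombination 0.031, remodellers 0.061, heterochromatin 0.026, intestinal markers -0.13, ovarian markers -0.093 and cell cycle -0.078. With −log10 q of at least 5: histone acetyltransferases -0.000135. With OVCAR8 and SKOV3 only: homologous recombination 0.048, end joining 0.21, remodellers 0.24, heterochromatin 0.13 and nuclear long non-coding RNAs -0.14. Without the RKO lists, in that order: 0.037, 0.055, 0.16, 0.17 and -0.18. Without the OVCAR8 and SKOV3 lists: writers -0.063, exosome -0.13, acetyltransferases -0.21, histone methylation -0.033, intestinal markers -0.13 and ovarian markers -0.063. With the protein-coding gene first: excision repair -0.00184 and ovarian markers -0.000455. The percent of regions lost minus that expected from peak strength, a comparison chosen after the data were seen, was -0.516 for ZNF genes in SKOV3 and 1.47 for remodellers in RKO, where minus the random median it was 3.52 and -7.83. Given peak strength, these stood at percentiles 99.7 and 7.80 of random lists, so ZNF genes stayed high and remodellers low among them. The cause was not tested.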

Other observations

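The tests, values and genes in this part were all chosen only after the data were seen. Regions held by all 4 ovarian control lists do not depend on which line a list came from. Of 11516 such regions, 68.6% had a peak in all 4 knockdown lists and 0.990% had none in any (interval 0.758 to 1.26). Of 8962 regions in all 4 knockdown lists, 3 had no control peak. Such a region had to be in the libraries labelled OVCAR8 knockdown, the shortest lists, which shared 95.9% of their peaks with SKOV3 control lists. The low number gained was therefore largely set in advance and is no contrast to the regions lost. The 114 lost regions were spread over many genes: CAMKMT, a calmodulin methyltransferase gene, lost 2 of 6 such regions and CCDC97 2 of 6, while G3BP1, a stress granule gene, and CDC25B, a cell cycle phosphatase gene, lost 1 of 1 each. CAMKMT had 11 peaks in LOVO control and 4 after knockdown, and 10 and 3 in RKO as labelled, while CCDC97 had 7 and 9 in LOVO. Loss was 2.52% of 436 regions between genes, on 11 lost regions, and 0.941% of 10416 regions in protein-coding genes. It was 0.980% of 408 regions in long non-coding RNA genes and 0.391% of 256 in other genes. Peak strength was not held alike between these classes. Of the regions that LOVO control also held, LOVO lost 23.2% of those lost in the ovarian lists and 11.98% of the others (odds ratio 2.26, interval 1.17 to 3.83, on 16 regions lost in both). The ratio was lower, with an interval that included 1, once peak strength was held alike: with terciles of ovarian control strength combined the odds ratio was 1.15 (interval 0.563 to 1.98), and with terciles of LOVO control strength 1.44 (interval 0.726 to 2.75). All 69 of the regions lost in the ovarian lists that LOVO control held were in the weakest ovarian tercile.

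The share of peaks at the caller's background floor, where the local background at the summit was no higher than its genome-wide level, separated the ovarian lists by condition. It was 70.2% to 71.2% in the 4 control lists and 51.7% to 56.3% in the 4 lists labelled knockdown. The mean difference was -16.9 percentage points (two-sided exact permutation p = 0.0556 with labels permuted within each line, the smallest that 36 arrangements can give). With the 8 lists as 1 stratum, the two-sided exact permutation p was 0.0286, the smallest that 70 arrangements can give. A lower share means that more of the listed knockdown peaks had a local background above the genome-wide level, in both lines as labelled. Whether this bears on the lower peak number was not tested for SKOV3. For the libraries labelled OVCAR8 knockdown, a higher input background was left open above.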
